A study of Mus musculus with 20 samples.

How the data were processed

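Poly(A) RNA was copied with oligo-dT and amplified by Smart-seq2 from batches of 10 to 15 mouse eggs or embryos, per the labels' protocols. The eggs were matured in culture after release from dbcAMP, fertilized in vitro and cultured in KSOM under 5% oxygen, per the labels' protocols. The 20 samples formed 7 groups of 3, apart from the B6CASTF1 2-cell embryos, of which 2 were used here. The direction of the B6CASTF1 cross is not given in the sources used here.

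The authors used bcl2fastq, kallisto, TopHat, Picard and DESeq2 with the genome build mm10, per the submitters' processing notes, which do not say which tool made which value. The authors' 5 comparison tables were made with DESeq2 1.18.1, per the file names. Per the file headers, the deposited values are a mean normalized count per gene, a log2 fold change with its SE, a shrunken log2 fold change, a Wald statistic (a score of the fold change over its SE), a p-value and an adjusted p-value. The mean normalized count was checked to be identical in the 3 deposited tables of C57BL/6J and in the 2 of B6CASTF1, so each strain was taken as fitted on its own. All 24411 gene symbols of the deposited tables were kept, and 23376 of them were found among GENCODE M21 symbols. No symbol began with the prefix of the mitochondrial genome, so 0 of the 13 mitochondrially encoded genes were measured.

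A gene counted as changed when the authors' adjusted p was under 0.05. No new test per sample was run, because the tables hold no values per sample. The depth of each sample is therefore unknown, and precision was read from the authors' SE. For genes with a mean count of at least 1000 in every stage, the SE of the 2-cell comparison over that of G2 against G1 zygotes had a median of 1.00 in C57BL/6J (1147 genes) and 1.12 in B6CASTF1 (1460 genes). The approximate mean of each stage was computed from the strain's mean count and its fold changes, weighted by the number of samples per stage.

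Named genes followed a rule set before the data were examined: the 6 highest and 6 lowest log2 fold changes among changed genes with a mean count of at least 100 and a name other than a predicted gene's, the 3 members of each list with the smallest p, and 10 genes named in advance (Nr5a2, Zscan4d, Zfp352, Hspa1a, Mos, Zp3, Gdf9, Btg4, Obox5 and Dux). Between strains the 5 largest differences in each direction with a mean count of at least 100 in both strains were named. Genes chosen after their values were seen are named as such.

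The 21 fixed gene lists were tested with cameraPR in limma 3.58.1 on the authors' Wald statistic, for lists with at least 5 tested members, with an inter-gene correlation of 0.01 and, as an alternative, 0.05. These p-values were adjusted by Benjamini-Hochberg over all lists and comparisons, and members were also adjusted over the list alone. The strain difference of each gene was the difference of the authors' log2 fold changes over the combined SE, with a normal p adjusted over all genes tested in both strains. Lists were compared between strains with cameraPR on the same ratio, a test added after the data were examined.

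The strain comparison and the list test were tested on simulated data. Of simulated strain differences of 2 and 4 on the log2 scale, 10% and 34% were found at the G2 against G1 step among 12517 genes, and 11% and 36% at the 2-cell step among 12573 genes, while 0.0325% and 0.0404% of unchanged genes were called. In 100 runs on 13264 genes of the G2 against G1 step in C57BL/6J, 2.37% of lists without change had a p under 0.05. The ribosomal list, with every member shifted by 1 SD of the statistic, was found in 100% of runs. The simulated genes were independent, so these runs say nothing on correlated list members. In the strain runs the changed genes were drawn at random, and the noise had exactly the SE that the test divides by. The low share of unchanged genes called therefore does not check whether the authors' SE are accurate.

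Transcript length, GC content and 3' UTR sequence came from the longest coding transcript of each gene in GENCODE M21. A cytoplasmic polyadenylation element was TTTTAT or TTTTAAT within the last 150 nt of the 3' UTR. Intervals of 95% came from 2000 bootstrap resamples, ranges of random lists from 10000 lists matched on transcript length, and shared libraries were simulated 1000 times for the covariance and 100 times for the signs. Alternatives were stricter thresholds, Bonferroni, a minimum mean count of 10 or 100, a minimum absolute log2 fold change of 1, recentring, an SE raised 1.5 times, ranks, and leaving out predicted genes. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.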

Results

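Poly(A) RNA was measured in mouse eggs and early embryos, in 20 samples of 7 groups, each sample a batch of 10 to 15 oocytes or embryos. The C57BL/6J samples covered 4 stages with 3 samples each: MII eggs, zygotes in G1, zygotes in G2, and 2-cell embryos in G2. MII eggs are arrested in metaphase of the second meiotic division. The F1 hybrid samples, called B6CASTF1 in the labels, covered G1 zygotes (3 samples), G2 zygotes (3 samples) and 2-cell embryos in G2 (2 samples used here). The title of the series names zygotic genome activation, the start of transcription from the embryo's own genome, and the nuclear receptor Nr5a2 (chromosome 1, 136842571 to 136960448, minus strand, GRCm38). The values analysed were the authors' own comparisons of consecutive stages, 5 tables of 24411 gene symbols each. These tables hold no values per sample, so the depth of each sample is unknown; the mean normalized counts summed to 19348115 in C57BL/6J and 20428114 in B6CASTF1. Among genes with a mean normalized count of at least 100, the median SE of the log2 fold change in the authors' deposited tables was 0.83 to 0.90 in C57BL/6J and 0.36 to 0.40 in B6CASTF1. The labels do not say whether the samples of a group came from separate females or days, so the p-values measure only the spread between these samples, which can be technical. Levels given per stage are approximate means worked out from each strain's mean and fold changes. The gene lists, the rule for naming genes and 10 single genes were set before the data were examined. Of the 13 mitochondrially encoded genes on these lists, 0 were measured in these tables. All changes are relative to the authors' normalization, which sets no scale for the total RNA of an embryo.

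**Figure D1:**
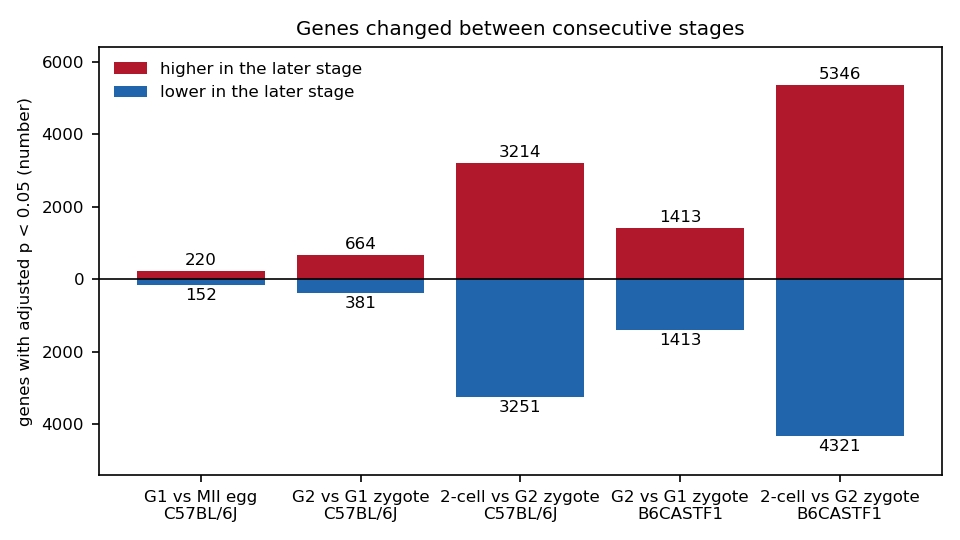
Number of genes with an authors' adjusted p under 0.05 in each comparison of consecutive stages, with genes higher in the later stage drawn upwards and genes lower in it drawn downwards. The step from G2 zygotes to 2-cell embryos had the most calls in both strains, 6465 in C57BL/6J and 9667 in B6CASTF1.

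The first comparison, G1 zygotes against MII eggs of C57BL/6J, asks how stored maternal RNA changes upon fertilization. Of 13551 genes tested, 220 rose and 152 fell. Mos, the kinase that holds the egg in meiotic arrest (chromosome 4, 3870657 to 3872105), fell by 3.42 on the log2 scale (SE 0.97, adjusted p = 0.019) in the authors' deposited table. The oocyte growth factors Gdf9 (log2 fold change -1.69, SE 0.46, adjusted p = 0.013) and Bmp15 (-0.96, SE 0.22, adjusted p = 0.0012) and the zona pellucida gene Zp3 (-0.98, SE 0.29, adjusted p = 0.030) fell as well in the authors' deposited table. Single members of large complexes moved apart: Atp5g1 (3.01, SE 0.35, adjusted p = 7.0e-15) and Cox4i1 (2.07, SE 0.24, adjusted p = 1.3e-14) rose while Cox6a1 (-1.91, SE 0.22, adjusted p = 3.6e-15) fell in the authors' deposited table, all 3 being subunits of the respiratory chain or ATP synthase.

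The largest changes in size were mostly of genes near 0 in 1 of the stages. Rsph9, Klhl41, Cyp2b23, Tbl2, Acer1 and Commd8 had the highest log2 fold changes and Cct6a, Sdr39u1, Clu, Eno1b, Tmed4 and Prps1 the lowest, and each had an implied level under 1 in MII eggs or G1 zygotes, so their folds are not given. Rsph9 reached only 0.281 in G1 zygotes, and Cct6a, Sdr39u1 and Clu started at 2.61, 1.77 and 1.81 in MII eggs. Among genes with an implied level of at least 10 in both stages, named here after their values were seen, Lsm10, a subunit of the U7 snRNP that processes histone mRNA, rose by 3.33 (SE 0.30, adjusted p = 1.4e-24) and Ndufb7 by 3.70 (SE 0.70, adjusted p = 2.4e-05) in the authors' deposited table. Ppp1r15b, a phosphatase subunit that acts on eIF2, fell by 4.11 (SE 0.87, adjusted p = 2.2e-04) in the authors' deposited table.

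By gene list, 6 of 43 tested oocyte-specific genes fell and 0 rose (6 and 1 adjusted over the list alone), with a median of -0.25. Of 38 meiotic and M-phase regulators, 2 fell, Mos and Wee1, and 0 rose (2 and 0 adjusted over the list alone). Wee1 was near 0 in G1 zygotes, with implied levels of 14.1 in MII eggs and 0.150 in G1. It was called higher again in G2 zygotes, at an implied level of 65.0. Of 48 spliceosome genes, only Lsm6 fell and 0 rose (3 and 0 adjusted over the list alone). As sets, the oocyte-specific list (adjusted p = 0.041, cameraPR in limma), the meiotic list (0.013) and the spliceosome list (0.0089) lay below other genes. With an inter-gene correlation of 0.05 these 3 were not past the threshold (adjusted p = 0.275, 0.148 and 0.148). All genes with a mean count of at least 100 had a median of -0.07 at this step.

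The other lists were not past the threshold as sets on the statistic, although the candidate activation factors lay below other genes when ranks were used (adjusted p = 0.0057, cameraPR). In the order rose and fell, with the counts adjusted over the list alone in parentheses, 10 and 8 of 74 nuclear-encoded oxidative phosphorylation genes changed (14 and 13 adjusted over the list alone) and 3 and 8 of 79 cytosolic ribosomal protein genes (7 and 11). The ribosomal protein genes that fell included Rplp1 (-2.26, SE 0.25, adjusted p = 1.7e-15) and Rpl41 (-2.42, SE 0.29, adjusted p = 1.9e-13) in the authors' deposited table. Changes were 2 and 3 of 31 proteasome genes (4 and 3), 3 and 2 of 40 translation factors (4 and 4), 1 and 3 of 44 RNA polymerase II genes (2 and 3), and 0 and 1 of 43 ribosome biogenesis genes (0 and 0). Of 32 candidate activation transcription factors 0 rose and 1 fell (2 and 1), of 43 mRNA decay genes 1 rose and 0 fell (1 and 0), and of 47 DNA replication genes 1 rose and 0 fell (2 and 0). One gene rose among 46 chromatin modifiers, Zfp57, which maintains imprints (1.57, SE 0.31, adjusted p = 7.9e-05 in the authors' deposited table), and 0 fell (1 and 0). Arg2 was the only one of 25 tested 2-cell-specific genes to rise (2.83, SE 0.53, adjusted p = 1.9e-05 in the authors' deposited table), and 0 fell (1 and 0). Of 29 heat shock and chaperone genes 1 rose and 1 fell (1 and 1), of 17 p53 and stress targets 1 rose and 0 fell (1 and 3), and 0 of 17 first-lineage genes changed (0 and 0). Marker lists of other cell types gave 0 calls among 10 cumulus and granulosa genes (0 and 0) and 4 blood and oviduct genes (0 and 0), and 1 of 10 testis genes fell, Meig1, from an implied level of 0.306 (0 and 1). Median, mean and test differed in sign for the proteasome, mRNA decay, chaperone and testis lists.

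The next comparison, G2 against G1 zygotes, covers the step within the zygote in which minor genome activation is known to take place. In C57BL/6J, 664 of 13264 tested genes rose and 381 fell. Cytosolic ribosomal protein genes lay above other genes as a set: 26 of 79 rose and 0 fell (30 and 0 adjusted over the list alone), with a median of 0.74 (cameraPR adjusted p = 2.3e-14). Rps25 (2.54, SE 0.34, adjusted p = 6.7e-11) and Rps6 (2.32, SE 0.35, adjusted p = 4.5e-09) were among them in the authors' deposited table. Of 74 nuclear-encoded oxidative phosphorylation genes, 16 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 0.69 (cameraPR adjusted p = 4.3e-07). They included Uqcr10 (1.58, SE 0.24, adjusted p = 4.3e-09) and Cox7b (2.58, SE 0.45, adjusted p = 1.4e-06) in the authors' deposited table. Gdf9 fell further (-3.13, SE 0.46, adjusted p = 2.8e-09), as did the oocyte linker histone H1foo (-2.98, SE 0.62, adjusted p = 9.8e-05) and Mos (-3.09, SE 0.97, adjusted p = 0.023), in the authors' deposited table.

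Both upward list shifts in C57BL/6J kept an adjusted p under the threshold with an inter-gene correlation of 0.05 (2.3e-05 and 0.0064). The 1402 other genes of similar transcript length to the ribosomal protein genes had a median of 0.56. With a trend on length, GC content and mean count removed, the ribosomal list's median was 0.25 (95% interval -0.07 to 0.34). No such trend was removed for the oxidative phosphorylation list, whose median in B6CASTF1 was 0.07. DNA methylation and chromatin modifiers lay below other genes, with 1 of 46 up and 5 down (1 and 6 adjusted over the list alone), a median of -0.61 and an adjusted p of 0.0051 in cameraPR, but an adjusted p of 0.128 with an inter-gene correlation of 0.05. Tet3, the oxidase of 5-methylcytosine in the paternal genome, was among those that fell (-1.15, SE 0.32, adjusted p = 0.0084) in the authors' deposited table. The 2-cell-specific genes had a median of 1.01, but only Gm6763 of 25 rose and 0 fell (1 and 0 adjusted over the list alone; cameraPR adjusted p = 0.192, and 0.015 on log2 fold changes with a mean count of at least 100). Nr5a2 had a log2 fold change of -0.76 (SE 0.57, adjusted p = 0.53) and Zscan4d of -0.05 (SE 1.27, adjusted p = 0.99) in the authors' deposited table. Dux, a multicopy gene that activates 2-cell transcripts, had a value of 7.59 with an SE of 4.09 (adjusted p = 0.31) in the authors' deposited table, with an implied level under 1 in G1.

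The largest folds in C57BL/6J again belonged to genes near 0 in 1 stage: Clu, Cct6a, Cdk10, Mylpf, Alb and Prps1 upwards and Fam69b, Actn4, Tor2a, Arrdc5, Pnp2 and Fzd7 downwards. All had an implied level under 1 in G1 or G2. Of the 1045 calls, 295 had such a stage. With at least 10 in both stages, and named after their values were seen, Rsph3b rose by 4.59 (SE 1.13, adjusted p = 0.0016) and the cyclin Y-like gene Ccnyl1 fell by 4.18 (SE 1.09, adjusted p = 0.0034) in the authors' deposited table. Lists without a set call changed as follows, with the counts adjusted over the list alone in parentheses. Of 43 oocyte-specific genes 1 rose, Dppa3, and 3 fell (1 and 3 adjusted over the list alone). Of 38 meiotic genes 5 rose and 2 fell (6 and 4), and of 43 mRNA decay genes 1 rose, Cnot1, and 0 fell (1 and 0). Of 48 spliceosome genes 6 rose and 2 fell (6 and 3), and of 31 proteasome genes 5 and 1 (5 and 3). Of 40 translation factors 7 rose and 1 fell (7 and 1), of 44 RNA polymerase II genes 4 and 1 (5 and 2), and of 43 ribosome biogenesis genes 2 and 3 (2 and 3). Of 32 candidate activation factors Dppa4 and Nanog rose, 2 in all, and 0 fell (3 and 0). Among 47 replication genes 1 rose and 1 fell (1 and 0), among 29 chaperones 1 and 1 (1 and 2), among 17 stress targets 2 and 0 (2 and 0), and among 17 first-lineage genes 2 and 1 (2 and 1). Cumulus and granulosa markers had 0 changes among 9 (0 and 0). Among 10 testis markers Meig1 rose and 0 fell (1 and 0), and among 3 blood and oviduct markers Epcam fell and 0 rose (0 and 1). Median, mean and test differed in sign for the ribosome biogenesis and chaperone lists.

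In B6CASTF1, 1413 of 14668 tested genes rose from G1 to G2 zygotes and 1413 fell. The 2-cell-specific genes rose: 8 of 25 passed the threshold upwards and 0 downwards (11 and 1 adjusted over the list alone), with a median of 1.24 (cameraPR adjusted p = 0.0016, and 0.038 with an inter-gene correlation of 0.05). Among them were Zscan4f (2.57, SE 0.51, adjusted p = 8.2e-06), Zscan4d (1.79, SE 0.48, adjusted p = 0.0023) and Dux (6.15, SE 1.51, adjusted p = 6.2e-04) in the authors' deposited table, all of them members of families of near-identical copies, whose reads the counting can have split. The difference of this list between the strains was not past the threshold at this step (adjusted p = 0.469, cameraPR). Dux stood at an implied level of 2.08 in G1 and 147 in G2. Genes that fell included Bub1b, a spindle checkpoint kinase (-3.95, SE 0.19, adjusted p = 2.8e-94), Gdf9 (-3.57, SE 0.17, adjusted p = 1.3e-89), H1foo (-3.48, SE 0.22, adjusted p = 9.2e-52) and Mos (-4.07, SE 0.32, adjusted p = 3.0e-35), in the authors' deposited table. Bub3, of the same checkpoint as Bub1b, rose (1.05, SE 0.14, adjusted p = 1.1e-12) in the authors' deposited table.

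Oocyte-specific genes of B6CASTF1 went both ways, with 9 of 47 up and 16 down (9 and 17 adjusted over the list alone) and a median of -0.17. As a set they lay below other genes (cameraPR adjusted p = 0.0018), but with an inter-gene correlation of 0.05 the adjusted p was 0.081. Of 78 ribosomal protein genes 25 rose and 6 fell (28 and 6 adjusted over the list alone), with a median of 0.46 (cameraPR adjusted p = 1.3e-04), and an adjusted p of 0.057 with an inter-gene correlation of 0.05. Of the 78 ribosomal protein genes tested in both strains, 16 rose in both, against 8.33 if the calls were independent. Nr5a2 had a log2 fold change of 0.80 (SE 0.51, adjusted p = 0.30) in the authors' deposited table.

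The genes with the extreme folds in B6CASTF1, Spink2, Mrpl33, Nup210l, Mttp, Mir17hg and Krt28 upwards and Snrnp35, Rab30, Cuedc2, Nppc, Ajuba and Ostm1 downwards, stood at an implied level under 2 in 1 of the stages. Named after their values were seen, Duxbl3 and Duxbl2, which had identical values of 3.57 (SE 0.44, adjusted p = 3.3e-14) in the authors' deposited table, and March7, a ubiquitin ligase (-4.08, SE 0.22, adjusted p = 4.2e-73 in the authors' deposited table), had at least 10 in both stages. Other lists were not past the threshold as sets on the statistic. In the order rose and fell, with the counts adjusted over the list alone in parentheses, 9 and 11 of 42 meiotic genes changed (10 and 14 adjusted over the list alone), and 6 and 12 of 44 mRNA decay genes (6 and 14). Changes were 9 and 14 of 47 replication genes (10 and 17) and 4 and 7 of 45 chromatin modifiers (4 and 7). For 32 proteasome genes the counts were 11 and 6 (12 and 7), for 48 spliceosome genes 7 and 11 (7 and 12), and for 41 translation factors 12 and 8 (13 and 9). They were for 46 RNA polymerase II genes 7 and 8 (8 and 10), for 46 ribosome biogenesis genes 9 and 2 (9 and 2) and for 75 oxidative phosphorylation genes 13 and 4 (14 and 5). Of 34 candidate activation factors 4 rose and 3 fell (4 and 3), with Dppa4 (2.39, SE 0.34, adjusted p = 4.9e-11) and Dppa2 (1.33, SE 0.20, adjusted p = 5.3e-10) up in the authors' deposited table. Of 31 chaperones 3 rose and 7 fell (3 and 7), of 21 stress targets 3 and 1 (3 and 1), and of 22 first-lineage genes 1 and 2 (1 and 2). Among markers of other cells, Ptgs2 of 10 cumulus and granulosa genes fell and 0 rose (0 and 1), and 0 of 8 testis genes (0 and 0) and 0 of 6 blood and oviduct genes (0 and 0) changed. Median, mean and test differed in sign for the translation factor, activation factor, first-lineage and testis lists.

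**Figure D2:**
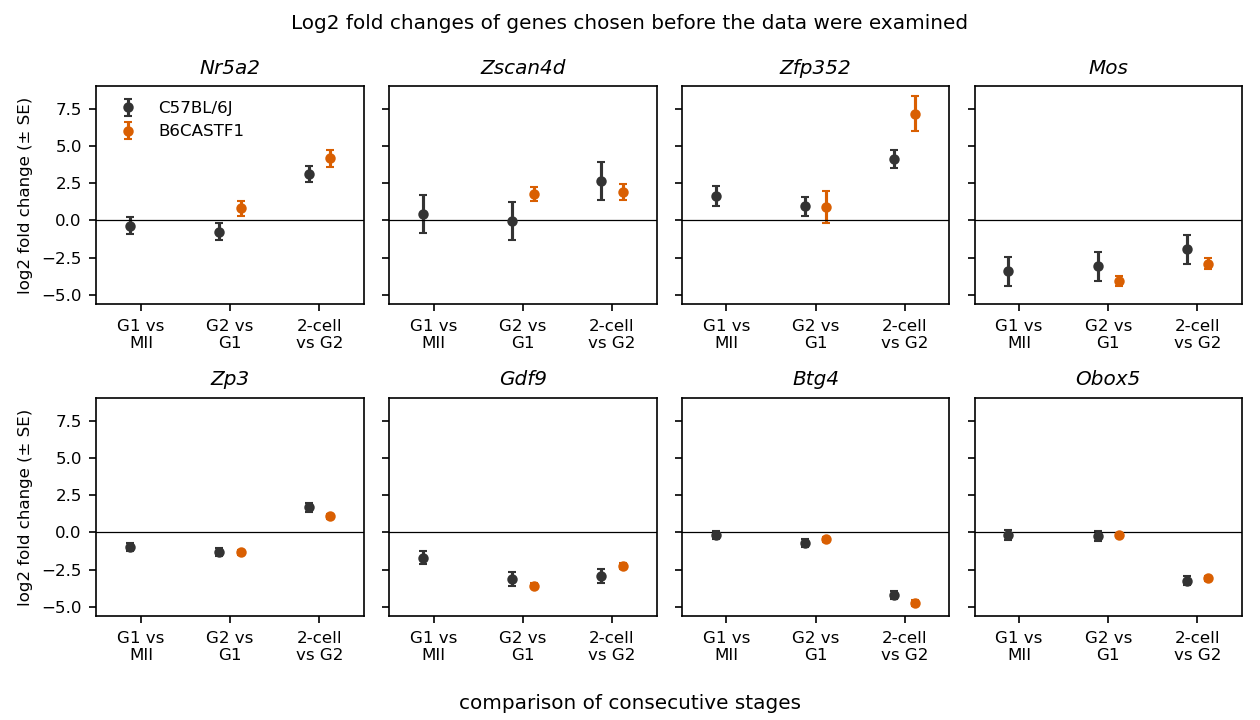
Log2 fold changes between consecutive stages of 8 genes chosen before the data were examined, from the authors' deposited tables; points are C57BL/6J (dark) or B6CASTF1 (orange) and bars are 1 SE. Nr5a2 rose at the 2-cell step, by 3.11 in C57BL/6J and 4.16 in B6CASTF1, while Btg4 and Obox5 fell there in both strains.

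The comparison of 2-cell embryos with G2 zygotes covers major genome activation. In C57BL/6J 3214 of 12839 tested genes rose and 3251 fell. Nr5a2 rose by 3.11 (SE 0.57, adjusted p = 2.5e-07) in the authors' deposited table, from an implied level of 83.9 to 724. Ribosomal protein genes rose almost without exception, 76 of 79 up and 0 down (76 and 0 adjusted over the list alone), with a median of 3.71 (cameraPR adjusted p = 6.2e-50). Oocyte-specific genes fell, 34 of 43 down and 1 up (34 and 1 adjusted over the list alone), with a median of -3.09 (cameraPR adjusted p = 5.1e-15). Within the Obox homeobox family the changes went apart: Obox6 rose by 10.88 (SE 0.66, adjusted p = 9.4e-58), while Obox2 (-5.47, SE 0.29, adjusted p = 8.0e-79) and Obox5 (-3.23, SE 0.33, adjusted p = 6.8e-21) fell in the authors' deposited table, with reads that close paralogs can share.

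Further lists lay above other genes at the 2-cell stage of C57BL/6J, to different extents. Of 25 2-cell-specific genes 15 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 3.23 (cameraPR adjusted p = 0.0041) and an adjusted p of 0.066 with an inter-gene correlation of 0.05. Zfp352, a retrogene zinc finger of the 2-cell embryo, rose by 4.11 (SE 0.62, adjusted p = 4.5e-10) and Zscan4d had a value of 2.65 (SE 1.26, adjusted p = 0.068) in the authors' deposited table. Ribosome biogenesis (27 of 43 up, 0 down; 27 and 0 adjusted over the list alone; median 2.46; cameraPR adjusted p = 3.8e-07), the proteasome (23 of 31 up, 2 down; 25 and 2 adjusted over the list alone; median 2.01; 8.7e-10) and oxidative phosphorylation (45 of 74 up, 7 down; 47 and 7 adjusted over the list alone; median 1.60; 6.4e-08) kept their calls with an inter-gene correlation of 0.05. Psmb5, a catalytic proteasome subunit, rose by 6.98 (SE 0.33, adjusted p = 2.5e-95) in the authors' deposited table. Translation factors (23 of 40 up, 2 down; 23 and 2 adjusted over the list alone; median 1.36; cameraPR adjusted p = 0.0018), RNA polymerase II genes (20 of 43 up, 3 down; 20 and 3 adjusted over the list alone; median 1.28; 0.011) and the spliceosome (17 of 48 up, 9 down; 17 and 9 adjusted over the list alone; median 0.54; 0.043) lost theirs. With that correlation their adjusted p was 0.070, 0.148 and 0.302.

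Among the genes that fell, Btg4, the adaptor of the deadenylase that removes maternal mRNA, dropped by 4.20 (SE 0.27, adjusted p = 6.4e-51) in the authors' deposited table, Bmp15 by 4.01 (SE 0.22, adjusted p = 4.3e-69) and Gdf9 by 2.92 (SE 0.46, adjusted p = 2.8e-09). Zp3, which had fallen at both earlier steps, rose by 1.69 (SE 0.29, adjusted p = 5.0e-08) in the authors' deposited table, and was the only oocyte-specific gene to do so. Mos had a value of -1.94 (SE 0.98, adjusted p = 0.086) in the authors' deposited table. The extremes in size, Sdr39u1, Rps27, Lst1, Yy1, Luzp4 and Mageb4 upwards and Lrrc36, Raet1d, Vmn2r25, Dpy19l1, Stau2 and Vti1b downwards, had an implied level under 1 in G2 zygotes or 2-cell embryos, as did 2084 of the 6465 calls. Yy1, a zinc finger transcription factor, was implied at 0.194 in G2 zygotes and 1455 in 2-cell embryos. Named after their values were seen, Timd2 (10.36, SE 1.09, adjusted p = 8.0e-20) and the tetraspanin Cd63 (10.41, SE 1.13, adjusted p = 1.0e-18) rose, and Oas1h (-9.63, SE 0.40, adjusted p = 5.3e-122) and Casp8, an initiator caspase (-9.01, SE 0.46, adjusted p = 2.8e-81), fell with at least 10 in both stages in the authors' deposited table.

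Lists without a set call in C57BL/6J went both ways, given as rose and fell with the counts adjusted over the list alone in parentheses: 14 and 9 of 31 activation factors (14 and 9), and 5 and 12 of 38 meiotic genes (5 and 12). Changes were 8 and 12 of 43 mRNA decay genes (8 and 12), 14 and 7 of 47 replication genes (14 and 7), and 16 and 9 of 46 chromatin modifiers (17 and 9). Of 29 chaperones 14 rose and 2 fell (14 and 2; cameraPR adjusted p = 0.052). Of 16 stress targets 7 rose and 3 fell (7 and 3), and of 16 first-lineage genes 7 and 4 (7 and 4). Cdkn1a, a cyclin-dependent kinase inhibitor, rose by 7.86 (SE 0.84, adjusted p = 4.0e-19) in the authors' deposited table. Of 7 cumulus and granulosa markers 1 rose and 3 fell (1 and 3), and of 10 testis markers 1 rose and 3 fell (1 and 3). Of 3 blood and oviduct markers, too few for a set test, 2 rose, Epcam and Cd74, and 0 fell (2 and 0). Median, mean and test differed in sign for the mRNA decay list.

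In B6CASTF1 5346 of 16128 tested genes rose from G2 zygotes to 2-cell embryos and 4321 fell. Nr5a2 rose by 4.16 (SE 0.56, adjusted p = 5.9e-13), from an implied level of 187 to 3341, and Zfp352 by 7.17 (SE 1.181, adjusted p = 4.9e-09) in the authors' deposited table. The 2-cell-specific genes rose, 21 of 25 up and 1 down (21 and 2 adjusted over the list alone), with a median of 3.92 (cameraPR adjusted p = 1.1e-04). Ribosomal protein genes rose in 76 of 78 cases with 0 down (76 and 0 adjusted over the list alone), with a median of 4.76 (cameraPR adjusted p = 2.2e-35). Ribosome biogenesis genes rose in 45 of 46 cases with 0 down (45 and 0 adjusted over the list alone), with a median of 3.49 (4.2e-21). Oocyte-specific genes fell in 39 of 47 cases and rose in 2 (40 and 2 adjusted over the list alone), with a median of -2.88 (3.1e-33). Gdf9 of this list fell by 2.24 (SE 0.20, adjusted p = 2.8e-29) and Btg4, of the mRNA decay genes, by 4.73 (SE 0.22, adjusted p = 2.3e-103) in the authors' deposited table. These 4 lists kept their calls with an inter-gene correlation of 0.05, the 2-cell-specific genes with an adjusted p of 0.0090.

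Candidate activation factors of B6CASTF1 were 18 up and 10 down of 35 (18 and 10 adjusted over the list alone), with a median of 1.82 (cameraPR adjusted p = 0.029, and an adjusted p of 0.211 with an inter-gene correlation of 0.05). Obox3 (8.73, SE 0.21) and Gabpa, an Ets-family factor (10.10, SE 0.27), had adjusted p-values given as 0 and Obox6 (10.25, SE 0.29) one of 1.2e-275 in the authors' deposited table. The spliceosome (34 up, 5 down of 48; 34 and 5 adjusted over the list alone; median 1.16; cameraPR adjusted p = 1.1e-05), the proteasome (26 and 3 of 32; 26 and 3; 1.85; 1.5e-06), translation factors (35 and 2 of 41; 35 and 2; 2.40; 5.8e-09), RNA polymerase II genes (30 and 6 of 46; 30 and 6; 1.64; 1.4e-05) and chaperones (24 and 4 of 31; 24 and 4; 2.503; 2.5e-05) shifted up and kept their calls with an inter-gene correlation of 0.05. Oxidative phosphorylation (52 and 10 of 75; 53 and 10; 1.75; 0.0032) and p53 and stress targets (14 and 1 of 22; 14 and 1; 2.58; 0.020) shifted up too, but with that correlation their adjusted p was 0.148 and 0.132. Hspa1a, an inducible Hsp70 gene known for early transcription, was implied at 0.165 in G2 zygotes and 478 in 2-cell embryos (adjusted p = 2.0e-13 in the authors' deposited table).

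Lists of B6CASTF1 without a set call went both ways at this step, again as rose and fell with the counts adjusted over the list alone in parentheses: 18 and 16 of 42 meiotic genes (18 and 16), and 15 and 18 of 44 mRNA decay genes (15 and 18). They were 22 and 14 of 48 replication genes (22 and 14), 18 and 17 of 46 chromatin modifiers (18 and 17) and 6 and 4 of 22 first-lineage genes (6 and 4). Markers of other cell types included blood and oviduct genes, of which 5 of 7 rose and 0 fell (5 and 0; median 6.35; cameraPR adjusted p = 0.040, and an adjusted p of 0.102 with an inter-gene correlation of 0.05). Cumulus and granulosa genes gave 2 up and 2 down of 13 (2 and 1) and testis genes 3 up and 3 down of 10 (3 and 3). The extremes, Snrnp35, Rps27, Cldn6, Uap1l1, H2-Q9 and Pgam2 upwards and Raet1d, Cyp2c69, Sorcs2, Col6a6, Zfp90 and Ccl11 downwards, had an implied level under 1 in G2 zygotes or 2-cell embryos. Timd2 rose by 10.77 (SE 0.33, adjusted p = 1.2e-230) and Casp8 fell by 6.85 (SE 0.36, adjusted p = 1.7e-79) in the authors' deposited table, both named after their values were seen. Median, mean and test differed in sign for the mRNA decay, meiotic, chromatin modifier and cumulus lists. The 2-cell step rested on 2 samples of this strain used here.

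**Figure D3:**
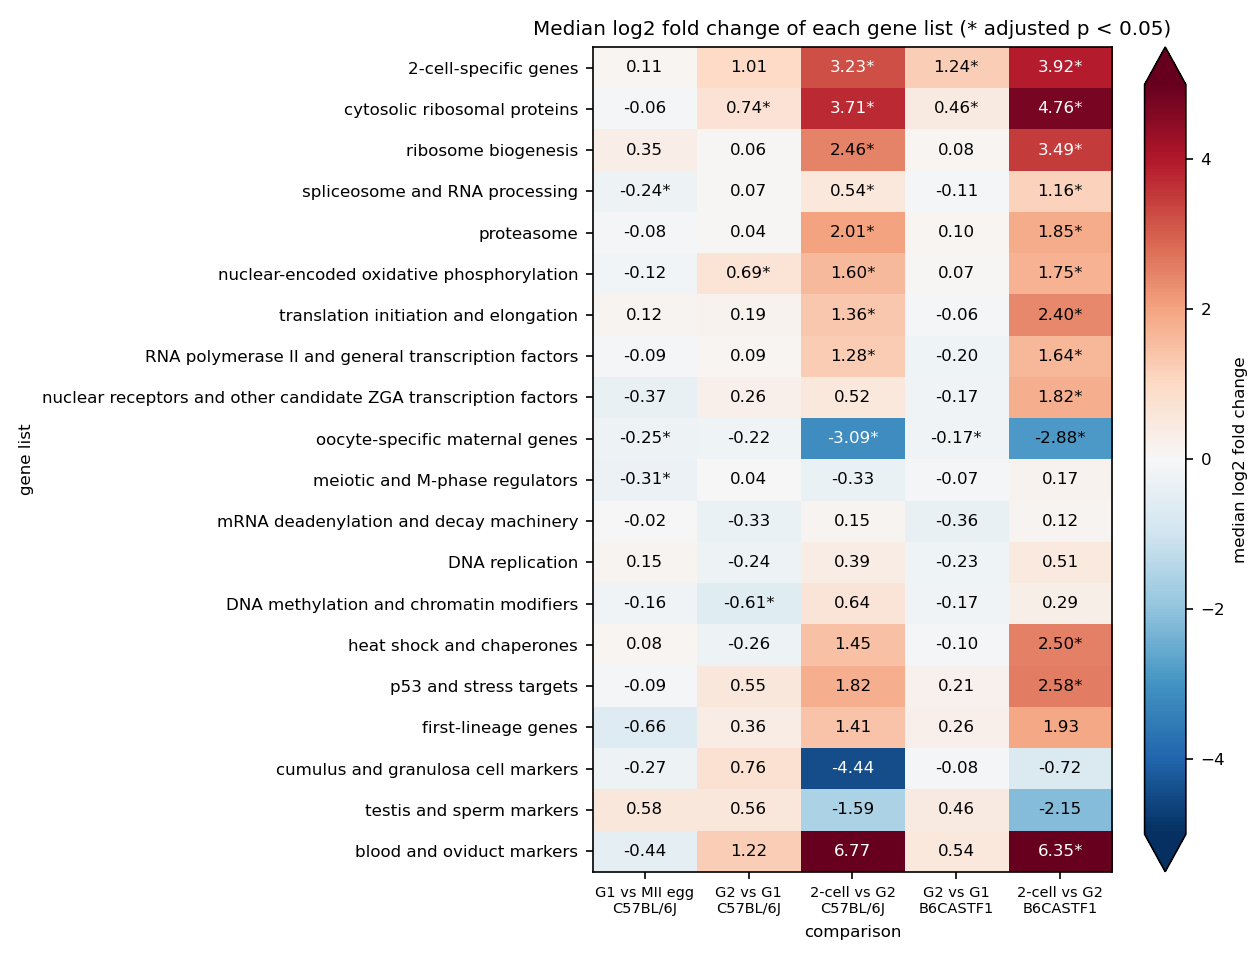
Median log2 fold change of the tested members of each gene list in each comparison, as color and number, with a star where cameraPR gave an adjusted p under 0.05 at an inter-gene correlation of 0.01; colors saturate beyond 5 in either direction. Ribosomal protein genes had medians of 3.71 and 4.76 and oocyte-specific genes of -3.09 and -2.88 at the 2-cell step of C57BL/6J and B6CASTF1.

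Set side by side, the strains shared much of the 2-cell step. Of 12573 genes tested in both, 2607 rose in both strains, against 1106 if the calls were independent, and 2316 fell in both, against 1018. Across these genes the log2 fold changes had a Pearson r of 0.695 and a Spearman rho of 0.764. At the G2 against G1 step, 285 of 12517 genes rose in both, against 66.2, and 155 fell in both, against 40.0, with an r of 0.198 and a rho of 0.353. These correlations are across genes, which are not independent replicates, and the 2 comparisons of a strain share its G2 libraries. For genes with a mean count of at least 100 in both strains, r was 0.824 at the 2-cell step and 0.409 at the earlier one. On the test statistic r was 0.740 and 0.4995, so its size depended on the measure. Of the C57BL/6J calls, 93.0% at the 2-cell step and 77.3% at the earlier one had the same sign in B6CASTF1.

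The difference between the strains' fold changes was tested per gene against the combined SE. At the G2 against G1 step 240 of 12517 genes differed, 130 of them higher in B6CASTF1 and 110 lower, and at the 2-cell step 2090 of 12573 did, 1457 higher and 633 lower. None of the genes named in advance that were tested in both strains differed at either step. In simulated data only 10% and 11% of differences of 2 in randomly drawn genes were found at the 2 steps, so equal changes are not shown. These shares do not describe each gene named in advance. At the G2 against G1 step the combined SE of those genes ranged from 0.33 for Zp3 to 4.36 for Dux. For Nr5a2 the difference, B6CASTF1 minus C57BL/6J, was 1.57 (combined SE 0.76, adjusted p = 0.47) and 1.05 (combined SE 0.80, adjusted p = 0.42) at the 2 steps, and for Zfp352 at the 2-cell step it was 3.07 (combined SE 1.33, adjusted p = 0.10). At the 2-cell step 124 genes were called with opposite directions in the strains and differed between them, 84 of them lower in C57BL/6J and higher in B6CASTF1. Nrbp1, an adaptor of ubiquitin ligases, had a log2 fold change of -8.21 (SE 1.28) in C57BL/6J and 2.22 (SE 0.15) in B6CASTF1 in the authors' deposited tables (adjusted p of the difference 2.6e-13), with an implied level under 1 in C57BL/6J 2-cell embryos. Prps1, an enzyme of nucleotide synthesis, had 9.44 (SE 1.63) and -0.73 (SE 0.30) at the earlier step in the authors' deposited tables (adjusted p of the difference 5.4e-07), with an implied level under 1 in C57BL/6J G1 zygotes. Strain and library series cannot be told apart, since each strain was fitted on its own. With the SE raised 1.5 times, 30 and 490 genes differed. With a mean count of at least 100, 105 genes differed at the earlier step, 39 of them higher in B6CASTF1 and 66 lower, so the balance of directions turned.

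Finally, genes were followed over consecutive steps. Of the 220 C57BL/6J genes that rose from MII eggs to G1 zygotes, 83 rose again from G1 to G2, against 11.01 if the calls were independent. Of the 152 that fell, 68 rose again, against 7.61, and 11 fell further, against 4.37, while 1 of the 220 that rose fell afterwards, against 6.32. Of the C57BL/6J genes that rose from G1 to G2, 309 rose on to the 2-cell stage, against 166, and 155 fell, against 168. Of those that fell, 206 rose, against 95.4, and 54 fell on, against 96.5. In B6CASTF1 the corresponding counts were 573, against 513, 534, against 415, 615, against 513, and 549, against 415. All of these B6CASTF1 counts lay above independence, in the same and in opposite directions alike. Genes measured precisely can be called more often at both steps. An excess over independence therefore does not by itself show coordinated change. Because consecutive comparisons share the middle libraries with opposite sign, 66.4% of genes changed sign in simulations without any effect, beside 50.8% observed at the first pair of C57BL/6J steps, 65.8% beside 51.9% at the second, and 64.6% beside 51.7% in B6CASTF1. Simulations without any effect gave at most 0 genes called at both steps, and part of the excess of genes that changed in opposite directions can come from the shared libraries.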

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

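The comparison of list shifts between strains and the depth test were chosen after the results were seen, as was the requirement that the bootstrap interval enter the verdict on transcript length; and so was the decision to leave open the explanations of genes that fell and then rose; the other tests here had predictions written beforehand.

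What drew attention was a difference between groups: the same step gave different fold changes in the strains, by a test of the difference itself. This held for 240 genes at the G2 against G1 zygote step and 2090 at the 2-cell step. At the earlier step the largest differences, B6CASTF1 minus C57BL/6J, were 11.04 for Polr3e, 10.28 for Krt28, 8.53 for Pnp2, 8.37 for Gm9125 and 8.25 for Actn4 upwards. Downwards they were -23.47 for Clu, -20.38 for Cct6a, -11.23 for Crip1, -10.23 for Gfod2 and -10.17 for Prps1. At the 2-cell step they were 12.37 for Cphx2, 10.91 for Birc2, 10.58 for Gabrp, 10.43 for Nrbp1 and 10.17 for Zfp414 upwards. Downwards they were -9.22 for 1110034G24Rik, -9.04 for Arrdc5, -8.68 for Pnp2, -8.16 for Fam207a and -8.10 for Ptges2. Each of these genes had an implied level under 1 in at least 1 stage of at least 1 strain, so the sizes and ranks are uncertain. The authors' shrunken log2 fold changes in the deposited tables were 5.71 and -1.22 for Clu and 2.41 and 1.54 for Cct6a in C57BL/6J and B6CASTF1.

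Lists differed between strains by their mean shift of the difference over its combined SE. At the earlier step the shifts were -0.66 for cytosolic ribosomal proteins, -0.68 for the spliceosome and -0.66 for oxidative phosphorylation (cameraPR adjusted p = 0.0060, 0.012 and 0.0060). At the 2-cell step they were 1.37 for ribosomal proteins, 1.06 for the spliceosome, -1.38 for the proteasome and 0.98 for RNA polymerase II genes (adjusted p = 2.4e-04, 0.016, 0.0078 and 0.041). With an inter-gene correlation of 0.05 the adjusted p of these 7 ranged from 0.240 to 0.370. No trend on transcript length was removed from these differences. Other genes of similar length to ribosomal protein genes had medians at the earlier step of 0.56 in C57BL/6J and 0.24 in B6CASTF1. At the 2-cell step these medians were 0.68 and 1.38. Whether transcript length carries these list differences was not tested.

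More genes changed from G1 to G2 zygotes in B6CASTF1 (2826) than in C57BL/6J (1045). Of the genes with a mean count above 0, 1834 had no p-value in C57BL/6J and 78 in B6CASTF1. Of these, 337 and 26 had a mean count above 100, so the strains also differed in which genes could be called. The reason for the missing p-values was not tested. The larger SE of C57BL/6J may account for the difference in calls. Shrunken B6CASTF1 effects redrawn with the C57BL/6J SE gave a median of 734.5 calls (647 to 797). With uncalled genes set to no change they gave 549 (499 to 604). Shrinkage can lower such counts, and every redraw lay below the 1045 observed in C57BL/6J. The redraws therefore do not reproduce that count. Deeper B6CASTF1 libraries stay open, since the ratio of summed mean normalized counts, 1.06, is no measure of depth. A difference between the strains themselves remains open as untested, and cannot be told apart from the library series.

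The median log2 fold change of ribosomal protein genes was positive, here called a rise, at G2 against G1 and at the 2-cell step in both strains. At G2 against G1, 26 of 79 passed upwards and 0 downwards in C57BL/6J, and 25 of 78 upwards and 6 downwards in B6CASTF1. The B6CASTF1 set call at that step was lost with the higher inter-gene correlation. Short or GC-rich transcripts (median length 906 against 2951 for all genes) might carry such a rise. After a trend on length, GC content and mean count was removed, the C57BL/6J median at G2 against G1 was 0.25. Its 95% interval was -0.07 to 0.34, and it lay within the middle 95% of random lists, -0.41 to 0.32. A shift shared by such transcripts therefore fits that rise, and whether it is technical was not tested. In B6CASTF1 the corrected median was 0.30 (0.09 to 0.55), beside 0.46 uncorrected and a middle 95% of random lists of -0.40 to 0.21. By the rule written beforehand, on the corrected median alone, length and GC content would not account for this rise. With the interval requirement added later, the explanations were not separated. At the 2-cell step the corrected median stayed at 2.64 (2.13 to 3.33) in C57BL/6J and 3.16 (2.92 to 3.43) in B6CASTF1. The middle 95% of random lists ended at 1.13 and 0.99, and the highest list reached 2.05 and 2.22. This trend therefore does not account for the rise there. Transcription of these genes in the embryo was not tested as an explanation.

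In C57BL/6J 68 genes fell from MII eggs to G1 zygotes and then rose, and 1 did the reverse. Noise of the shared G1 libraries could add to this, but the covariance of the fold changes, -0.48 beside -0.56 (-0.62 to -0.49) in simulations without effect, is over 8300 genes and does not settle it for these 69. Simulations without effect gave 0 genes called at both steps, and few calls are possible there by construction. Levels near 0 could add to it too, but the 53.6% with an implied level under 1 in G1, 37 genes, decides nothing, since that level was worked out from the folds that chose them. No biological explanation was tested.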

How the results depend on the processing

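The alternatives that leave out genes implied under 1 and the list tests between strains were chosen after the data were seen. No called gene among the named ones and no called list changed direction, and for genes only recentring could have changed it. The balance of the strain differences at G2 against G1 did turn. Under Bonferroni the changed genes numbered 137 (G1 zygote against MII egg), 254 and 2594 in C57BL/6J and 864 and 5405 in B6CASTF1 (G2 against G1, then 2-cell), fewer by construction. At an adjusted p under 0.01 there were 622 for G2 against G1 in C57BL/6J, 121 and 1287 strain differences, and 101 and 393 genes called at consecutive C57BL/6J steps. With an absolute log2 fold change of at least 1 there were 1785 for G2 against G1 in B6CASTF1, 59.0% of them higher, and 1296 at its consecutive steps. Of 31 list calls, 17 remained with an inter-gene correlation of 0.05 and on log2 fold changes with a mean count of at least 100, which could be tested for 30 of them, 14 remained and 16 were lost, with 16 calls in all; the cause was not tested. Lists called only under an alternative were candidate activation factors (G1 against MII, ranks, cameraPR adjusted p = 0.0057), chaperones (C57BL/6J 2-cell, ranks, 0.0015), 2-cell-specific genes and stress targets (C57BL/6J G2 against G1, log2 fold changes, 0.015 and 0.0035) and the proteasome (B6CASTF1 G2 against G1, recentred, 0.025). Strain differences at G2 against G1 numbered 105 with a mean count of at least 100, 30 with the SE raised 1.5 times and 95 without genes implied under 1, with 37.1%, 66.7% and 36.8% higher in B6CASTF1 instead of 54.2%. At the 2-cell step they numbered 490 with the SE raised and 1218 without genes implied under 1, with 81.0% and 60.2% higher instead of 69.7%; the cause was not tested. The correlation between strains was 0.409 and 0.824 with a mean count of at least 100, and 0.4995 and 0.740 for the test statistic; the cause was not tested. Of 322 calls of named genes, counted per comparison, 244 held under Bonferroni and 78 did not, and 320 held when recentred, 2 did not and 4 were gained. Of the list calls 26 held with ranks and 29 when recentred. Of the 20 named strain differences 8 held with the SE raised and 12 did not. No paired analysis was possible because the tables hold no values per sample. For the same reason leave-one-out fits, another count tool or normalization, pseudocounts, other splits of samples and an estimated inter-gene correlation were not run, and recentring on mitochondrial genes was not run with 0 of them measured. Depth per sample is unknown, so its limit was read only from the SE.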

Other observations

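The test of AT-rich 3' ends was chosen after the polyadenylation result was seen; the test of the polyadenylation element itself had its prediction written beforehand.

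Of the DNA methylation and chromatin modifiers, 13 rose in both strains at the 2-cell step and 8 fell in both, out of 45 tested in both. If the calls were independent, 5.67 and 3.40 would do so. Over all 12573 genes tested in both, 2607 rose and 2316 fell in both strains, so shared changes were common beyond this list. Dnmt1, the maintenance methyltransferase, fell by 2.81 (SE 0.37, adjusted p = 1.1e-12) in C57BL/6J and by 4.27 (SE 0.16, adjusted p = 3.2e-164) in B6CASTF1 in the authors' deposited tables. Zfp57, which keeps imprints, fell by 3.29 (SE 0.32, adjusted p = 9.6e-24) and by 5.09 (SE 0.26, adjusted p = 1.3e-82) in the authors' deposited tables, after rises of 1.57 from MII eggs to G1 zygotes in C57BL/6J and 1.07 from G1 to G2 in B6CASTF1. Tet3 fell by 3.90 (SE 0.33, adjusted p = 4.8e-30) in C57BL/6J and fell by 4.54 (SE 0.27, adjusted p = 8.7e-61) in B6CASTF1 in the authors' deposited tables. The histone demethylase gene Kdm5b rose by 4.17 (SE 0.97, adjusted p = 7.8e-05) and by 5.25 (SE 0.21, adjusted p = 2.5e-131) in the authors' deposited tables.

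Among marker genes of other cells, Cyp19a1 of granulosa cells fell by 7.64 (SE 0.76, adjusted p = 2.3e-22) in C57BL/6J and by 5.77 (SE 0.36, adjusted p = 1.2e-56) in B6CASTF1 at the 2-cell step in the authors' deposited tables. Its implied level was 1597 in MII eggs and 810 in G2 zygotes of C57BL/6J. Of the 27 measured cumulus and granulosa genes, only Cyp19a1 had a mean count of at least 100 in C57BL/6J. In B6CASTF1 5 of them did. Epcam rose by 8.89 (SE 0.89, adjusted p = 4.9e-22) and 6.35 (SE 0.41, adjusted p = 1.5e-53) and Cd74 by 6.77 (SE 1.46, adjusted p = 1.7e-05) and 9.38 (SE 0.70, adjusted p = 3.4e-40) in the authors' deposited tables. Amhr2, of the same list as Cyp19a1, rose at this step from implied levels of 0.193 to 286 in C57BL/6J and 0.594 to 891 in B6CASTF1 (adjusted p = 0.0023 and 2.7e-18 in the authors' deposited tables). Ptgs2 of that list rose in B6CASTF1 from 0.895 to 203 (adjusted p = 7.6e-06 in the authors' deposited table). The hemoglobin gene Hba-a1 rose by 9.09 (SE 0.69, adjusted p = 3.0e-38) in B6CASTF1 in the authors' deposited table.

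Of the 68 genes that fell and then rose in C57BL/6J, 21 had an implied level of at least 100 in MII eggs, G1 and G2 zygotes, and those given here were named after their values were seen. H3f3a, a histone H3.3 gene, fell by 2.12 (SE 0.17, adjusted p = 1.8e-33) into G1 and rose by 1.15 (SE 0.17, adjusted p = 1.6e-09) into G2, and the calmodulin gene Calm2 fell by 1.53 (SE 0.24, adjusted p = 4.7e-08) and rose by 2.62 (SE 0.24, adjusted p = 2.3e-24), in the authors' deposited table. Haus1 of the augmin complex fell by 2.22 (SE 0.37, adjusted p = 3.2e-07) and rose by 3.52 (SE 0.37, adjusted p = 1.3e-18) in the authors' deposited table.

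Because oligo-dT captures poly(A) tails, changes of tail length in stored mRNA could appear as changes of level, and genes with a cytoplasmic polyadenylation element near the 3' end were compared with genes without. The difference of median log2 fold changes, with minus without, was -0.18 (95% interval -0.22 to -0.14) from MII eggs to G1 zygotes, over 2069 and 5793 C57BL/6J genes. From G1 to G2 it was -0.28 (-0.34 to -0.23) in C57BL/6J and -0.29 (-0.33 to -0.25) in B6CASTF1, over 2342 and 6715 genes. Each had a permutation p of 0.0001, the smallest that 10000 permutations can give, over genes that are not independent replicates. From G1 to G2 21.7% of B6CASTF1 genes with an element fell and 11.9% of those without, and 4.06% and 2.35% in C57BL/6J, but from MII eggs to G1 zygotes it was 1.353% with and 1.536% without. Genes with an element rose less often at each step, 1.16% against 2.73% from MII eggs to G1 zygotes, then 4.30% against 7.51% in C57BL/6J and 7.86% against 14.2% in B6CASTF1.

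AT-rich 3' ends or transcript length might carry the same difference, since the searched window had a GC content of 31.3% with and 38.7% without an element in C57BL/6J. After a trend on length, 3' UTR length and GC content was removed, the difference was -0.089 (-0.12 to -0.05) from MII eggs to G1 zygotes and -0.17 (-0.24 to -0.11) from G1 to G2 in C57BL/6J, which left both explanations possible. In B6CASTF1 it was -0.21 (-0.25 to -0.17), which composition and length do not account for as far as this trend goes. Tail length itself was not measured, and decay of these transcripts would look the same.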
